A study of Mus musculus with 8 samples.

How the data were processed

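RNA-seq libraries from the hippocampus of control and Jade2-knockout mice were compared, with 4 libraries per group. Per the labels, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit. Reads were aligned with HISAT2 to mm10 and quantified with Cuffdiff, per the submitters' processing notes, which give no versions. Transcript abundances were deposited by the authors with no unit named, and they are taken as FPKM. The log2 fold changes and p-values are also the authors', from the deposited table, and the test behind them is not given in the sources used here. For 274 transcripts above 0.5 in every library, the authors' log2 fold change had a slope of 1.00 on the difference of mean log2 abundance.

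The deposited table is a selected list. It holds 1679 transcripts of 1404 loci, each with an authors' unadjusted p under 0.05 and an absolute log2 fold change of at least 1. The ratio of adjusted to unadjusted p implies adjustment over 104721 transcripts, so 1.60% of them are listed. Of the listed transcripts 691 have a value of 0 in at least 1 library, 18 are at 0 in all 4 knockouts and 20 in all 4 controls. A value of 0 can be a failed estimate or a different division of reads among models. Totals of such a list are not library depth, and no counts were used, so depth and counting error are unknown.

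Of the listed transcripts 1138 have an Ensembl identifier. Compared with GENCODE M21 on GRCm38, 1136 were found and 1118 had identical coordinates. The other 541 are merged models. Of these 103 took the gene name of an annotated transcript in their locus, 339 were named by position on the same strand with at least 50% reciprocal overlap, and 99 stayed unnamed. Strand use in quantification is not given in the sources used here, so overlapping and antisense genes, and ribosomal protein genes with processed pseudogenes, are uncertain.

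Groups came from the labels. The deleted gene was tested with a two-sided exact permutation test on log2(FPKM + 0.5). Transcripts with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3, with a variance trend, two-sided, at an adjusted p of 0.05. Fold changes on this scale understate the change of low transcripts. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

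The groups, the limma model, the gene lists, the naming rule and most alternatives were set before the data were examined. Other choices followed from what the table turned out to hold. The plan assumed a table of all genes. Transcripts were therefore tested in place of genes, and Benjamini-Hochberg adjustment was made over 104721 transcripts, because adjustment within a list selected on p is not valid. The variance prior still comes from selected transcripts. List members were ranked by the authors' unadjusted p, since many have a mean under 1 FPKM and no limma result. Adjustment over listed transcripts only, unmoderated variance, sums per locus and the left-out libraries for the Jade2 locus sum were added after seeing the data.

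The procedure was tested on simulated data of 104721 transcripts, 4 against 4, with 2883 listed and 1515 tested. Adjustment over all transcripts gave 98 calls, 11 of them false. Recovery was counted only among changed transcripts with a mean of at least 1. It was 0% for true log2 changes of 1, 37.5% for 2, 71.4% for 3 and 90% for 4. Adjustment over listed transcripts only gave 1511 calls, 1385 of them false. With the spread raised to 1.5 times, 39 calls held 7 false ones, and recovery was 0% for log2 changes of 1, 2.8% for 2, 11.6% for 3 and 52% for 4. With adjustment over all transcripts the false share was above the 0.05 aimed at for each spread. Simulated means and spreads were drawn from the listed transcripts, which were selected on p. The simulated spread may therefore be too small and the recovery too high.

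Named transcripts are those of Jade2, then for each direction the 12 with the largest log2 change past the threshold or, with fewer than 6, the 6 with the smallest p, then up to 4 members of each list. Transcripts with an authors' adjusted p under 0.05 were named as well, a choice made after the values were seen. The lists cover the JADE and HBO1 and LSD1-CoREST complexes, synapse, plasticity, channel, guidance and adhesion genes, neurogenesis, hippocampal subfields, other cell types and neighbouring tissue, stress, ribosomal and respiratory genes, genes flanking Jade2 and sex-linked check genes. Results for a few items, 1 of the lists among them, are not reported here, although the overall counts include them. Alternatives were 2 other pseudocounts, no filter or a mean of at least 5, other scalings, a replicate block, each library left out, and other limma settings.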

Results

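Hippocampal RNA was sequenced from 8-week-old C57BL/6 mice, with 4 wild-type control libraries and 4 Jade2-knockout libraries. Jade2 is a PHD-finger protein known as a partner of the histone acetyltransferase HBO1. The table analysed here is a selected list of 1679 transcripts, each with an abundance per library. Its abundance unit is not named, and values are given here as FPKM because the submitters' processing notes name Cuffdiff. The largest unadjusted p in the authors' deposited table is 0.0498, and the smallest absolute log2 fold change is 1.00. Transcripts outside that list were not analysed here, so neither gene totals nor the unselected background can be given. Read depth is unknown because the table holds no counts. Median listed abundance per library was between 0.77 and 0.90 FPKM. The labels do not say that the libraries of a group came from separate animals, so p-values from comparisons of libraries measure the spread between these samples.

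The first comparison asked whether the targeted gene differed between the groups in every library. The annotated Jade2 transcript ENSMUST00000109091 (mm10, chromosome 11, 51813460 to 51857396, minus strand, protein coding) was listed at 0 in all 4 knockout libraries. In the control libraries it stood at 2.66, 2.66, 1.41 and 5.05 FPKM for replicates 1 to 4. On the log2(FPKM + 0.5) scale this annotated transcript fell by 2.68 (SE 0.315, n = 4 per group, two-sided exact permutation p = 0.0286, the smallest that 70 assignments can give). The size of this difference is set largely by the pseudocount, as the knockout group is listed at 0.

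The Jade2 locus was not empty in the knockout libraries. The merged transcript model MERGE.3721.1, which spans chromosome 11 from 51813448 to 51857690, stood at 8.33, 3.59, 7.82 and 12.3 FPKM in knockout replicates 1 to 4 and was listed at 0 in all 4 controls. Models MERGE.3721.3 and MERGE.3721.4 were also listed at 0 in all 4 controls, with knockout means of 4.31 ± 2.61 and 1.85 ± 1.12 FPKM (SD, n = 4). Model MERGE.3721.8 had the opposite pattern, with a control mean of 8.09 ± 4.55 FPKM (SD, n = 4) and a highest knockout value of 0.00225 FPKM. The 5 listed transcripts of the locus summed to 14.2 ± 4.71 FPKM in the knockout and 11.03 ± 5.28 FPKM in the control (SD, n = 4 per group, two-sided exact permutation p = 0.457). The exons of the merged models are not given in the sources used here, so which part of Jade2 each of them holds is unknown.

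**Figure D1:**
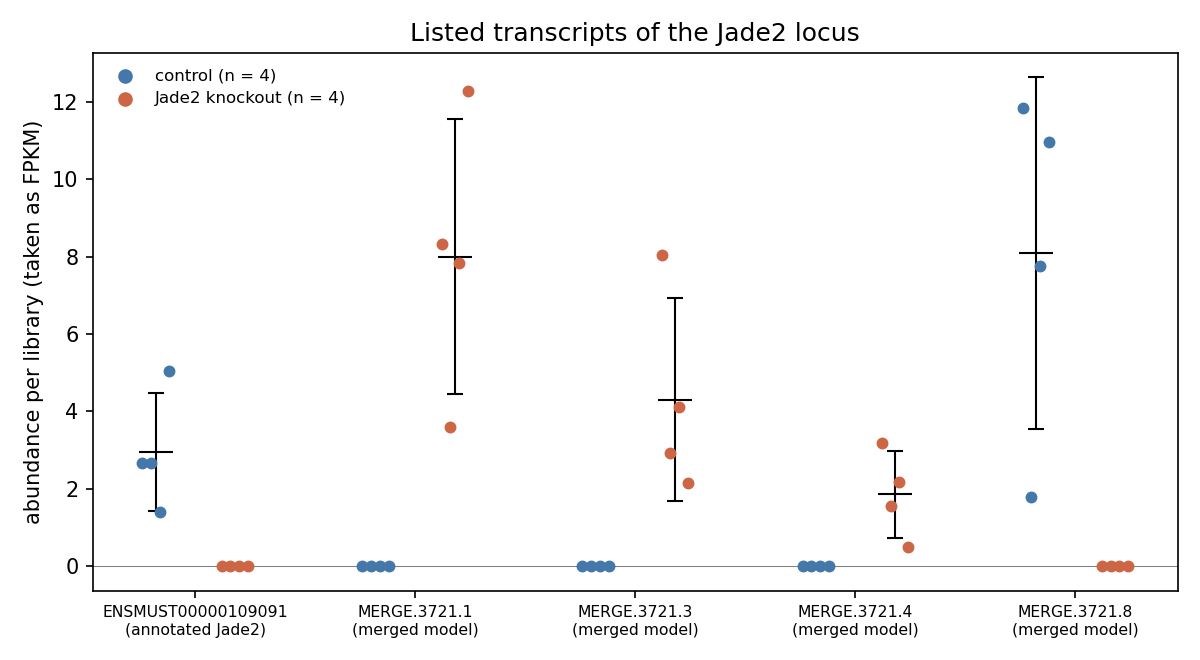
Abundance (taken as FPKM) of the 5 listed Jade2 locus transcripts in each control and knockout library; points are libraries, horizontal marks are means and bars are SD (n = 4). The annotated transcript is at 0 in all 4 knockout libraries, while MERGE.3721.1, MERGE.3721.3 and MERGE.3721.4 are at 0 in all 4 control libraries.

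The second comparison asked which transcripts differed between knockout and control hippocampus. Outside the Jade2 locus, isoforms of Lcp1, Sobp, Spcs1, Eif4e, Nbas and Upp1 were higher in the knockout, and isoforms of Zfhx4, Ctnnd1, Matr3 and Synj1 were lower, as called in the authors' deposited table. Lcp1 ENSMUST00000145303, an isoform of the actin-bundling protein L-plastin, averaged 2.71 ± 0.201 FPKM in the knockout (SD, n = 4) and was listed at 0 in all 4 controls. The Sobp model MERGE.2235.4 averaged 4.69 ± 1.49 FPKM in the knockout (SD, n = 4) and was likewise listed at 0 in all 4 controls. Synj1 ENSMUST00000118390, an isoform of the phosphoinositide phosphatase synaptojanin 1, averaged 1.25 ± 0.386 FPKM in the knockout and 12.5 ± 2.84 FPKM in the control (SD, n = 4 per group). Matr3 ENSMUST00000187389, from the gene of an RNA-binding nuclear matrix protein, averaged 5.04 ± 1.91 FPKM in the control (SD, n = 4) and 0.00217 FPKM in the knockout.

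Spcs1 ENSMUST00000228736, of a signal peptidase complex subunit, averaged 2.71 ± 0.804 FPKM in the knockout and 0.0199 ± 0.00173 FPKM in the control (SD, n = 4 per group). Eif4e ENSMUST00000200020, of the cap-binding translation initiation factor, averaged 2.12 ± 1.31 FPKM in the knockout (SD, n = 4) and 0.0023 FPKM in the control. The Nbas model MERGE.5267.3 averaged 2.27 ± 1.05 FPKM in the knockout (SD, n = 4). Upp1 ENSMUST00000101525, of uridine phosphorylase 1, averaged 0.840 ± 0.405 FPKM in the knockout (SD, n = 4) and 0.00588 FPKM in the control. Zfhx4 ENSMUST00000176383, of a zinc finger homeobox transcription factor, averaged 1.98 ± 0.431 FPKM in the control (SD, n = 4) and was listed at 0 in all 4 knockouts. Ctnnd1 ENSMUST00000145312, a noncoding isoform of the p120 catenin gene, averaged 0.0338 ± 0.00791 FPKM in the knockout and 1.43 ± 0.210 FPKM in the control (SD, n = 4 per group). An unnamed model, MERGE.15492.1 on chromosome 3, averaged 1.61 ± 0.794 FPKM in the control (SD, n = 4) and was listed at 0 in all 4 knockouts.

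**Figure D2:**
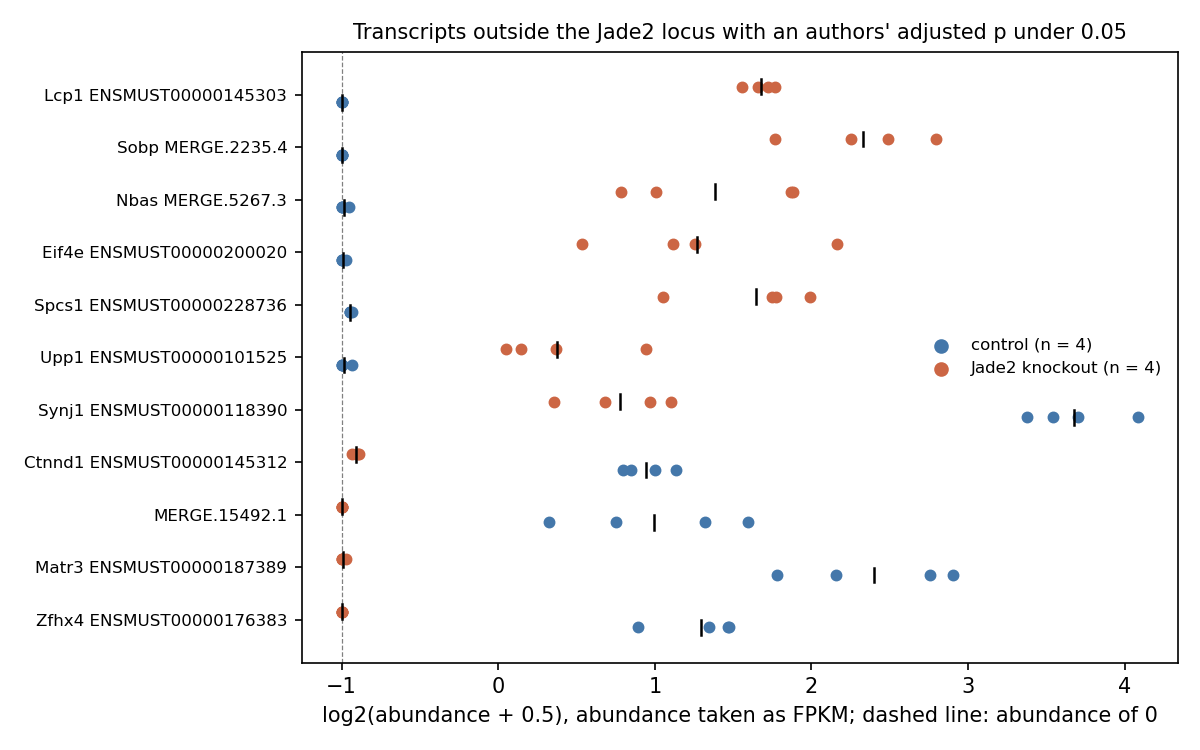
Abundance on a log2(FPKM + 0.5) axis of the 11 transcripts outside the Jade2 locus with an adjusted p under 0.05 in the authors' deposited table; points are libraries (n = 4 per group), vertical marks are group means and the dashed line is an abundance of 0. In each of the 11, all 4 knockout values lie on one side of all 4 control values.

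Of the 1679 transcripts, 815 were higher and 864 lower in the knockout. The authors' deposited table gives an adjusted p under 0.05 for 15 of them, 9 higher and 6 lower, and under 0.1 for 22. Adjusted p in the authors' deposited table was 6.27e-05 for Lcp1, 0.000359 for Zfhx4, 0.000757 for Sobp, 0.00529 for Matr3 and 0.0137 for Synj1. Of those 15, 4 belong to the Jade2 locus. For 1548 transcripts the authors' deposited table gives an adjusted p of 0.888. The adjusted p-values imply at most 5870 of the 104721 transcripts with an authors' unadjusted p up to 0.0498. Chance alone would give about 5216, so an unadjusted p up to 0.0498 is weak evidence of a difference for a single transcript. Both numbers leave out the fold change that listing also requires, for which no chance count was made. The ranks implied by the authors' deposited table place the Nbas model 35th among all tested transcripts but 14th in the list, so the list holds only part of the transcripts with p that small.

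Listed transcripts with a mean of at least 1 FPKM were tested again from the library values with limma. Adjustment was over the 104721 transcripts implied by the authors' adjusted p-values. Of the 15 with an adjusted p under 0.05 in the authors' deposited table, 10 were tested in this way. The others, among them the Zfhx4, Ctnnd1 and Upp1 isoforms, had a mean below 1 FPKM. Of 849 transcripts with a mean of at least 1 FPKM, 0 passed an adjusted p of 0.05 in limma, 3 passed 0.1, and 599 had an unadjusted p under 0.05, a number fixed largely by the selection of the list. The 3 were Jade2 MERGE.3721.1, Sobp MERGE.2235.4 and Matr3 ENSMUST00000187389, each with a limma adjusted p of 0.0760. With no abundance filter limma called 7 transcripts, of Lcp1, Sobp, Matr3, Jade2, Zfhx4, Spcs1 and, outside the naming rule, Fermt3, and without control replicate 2 it called 4. Without control replicate 1 or without control replicate 4 it called 1.

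Other transcripts with the smallest p in limma did not pass. Dis3l ENSMUST00000120760, from the gene of a cytoplasmic exosome exonuclease, averaged 3.38 ± 0.917 FPKM in the knockout and 0.152 ± 0.244 FPKM in the control (SD, n = 4 per group). Mtcl1 ENSMUST00000097291, from the gene of a microtubule crosslinking factor, averaged 0.180 ± 0.358 FPKM in the knockout and 4.88 ± 1.54 FPKM in the control (SD, n = 4 per group). Fam171a1 ENSMUST00000115099 averaged 1.11 ± 0.679 FPKM in the knockout and 16.4 ± 5.87 FPKM in the control (SD, n = 4 per group). Some of these genes also had a listed isoform in the other direction, named after the values were seen. Fam171a1 ENSMUST00000062934 averaged 14.02 ± 4.48 FPKM in the knockout and 0.955 ± 1.26 FPKM in the control, Synj1 ENSMUST00000154276 averaged 37.4 ± 11.1 and 13.4 ± 5.82 FPKM, and Zfhx4 ENSMUST00000026284 averaged 1.81 ± 1.10 and 0.0163 ± 0.0209 FPKM (SD, n = 4 per group).

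The third comparison asked how fixed gene groups of chromatin, synapse and cell identity were represented among the listed transcripts. No member of any of the 36 lists passed limma when adjusted over all 104721 transcripts. Counts adjusted over the list alone, given below, come from transcripts already selected on p and are not independent evidence. The list here is the fixed gene list. Where it had a single tested member there was nothing to adjust over, and its unadjusted limma p is described in place of such a count.

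Among the chromatin lists, the JADE and HBO1 complex had 6 listed transcripts, 3 higher and 3 lower, of which 5 were from the Jade2 locus and 4 passed when adjusted over the list alone. The other was Jade3 ENSMUST00000043693, named after its values were seen, at 0.198 ± 0.396 FPKM in the knockout and 0.953 ± 0.534 FPKM in the control (SD, n = 4 per group). The LSD1-CoREST list had 3, 2 higher and 1 lower, and its 1 tested member, Zmym3, had an unadjusted limma p above 0.05. Retained-intron transcripts of its members Kdm1a (ENSMUST00000139690), the histone demethylase LSD1, and Hdac1 (ENSMUST00000150105) averaged 0.884 ± 0.0691 and 0.868 ± 0.0953 FPKM in the knockout, against 0.384 ± 0.101 and 0.318 ± 0.0760 FPKM in the control (SD, n = 4 per group).

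Among the synaptic lists, the excitatory postsynapse had 6 listed transcripts, 4 higher and 2 lower, and 2 of 5 tested passed adjusted over the list alone. Camk2b ENSMUST00000090443, of a synaptic calcium-dependent kinase, averaged 141 ± 42.3 FPKM in the knockout and 61.3 ± 26.7 FPKM in the control (SD, n = 4 per group). Dlgap1 ENSMUST00000133983, of a postsynaptic scaffold protein, averaged 0.689 ± 0.472 FPKM in the knockout and 2.57 ± 1.43 FPKM in the control (SD, n = 4 per group). Presynaptic vesicle release had 1 higher and 3 lower, the lower being isoforms of Unc13b, Erc2 and Nrxn2 (ENSMUST00000128272). Its 1 tested member was the higher one, Nrxn2 ENSMUST00000113461, with an unadjusted limma p under 0.05. This isoform was at 3.55 FPKM in control replicate 1 and at 0 in the other controls. The GABA synapse list had 1 of each direction, with Gabbr1 ENSMUST00000173823 higher, and none was tested. Voltage-gated channels had 9 higher and 3 lower, among them isoforms of Kcnh7, Scn8a and Kcna2 at higher means, and 0 of 5 tested passed in limma adjusted over the list alone, with 3 at an unadjusted p under 0.05. Long-term potentiation signalling had 2 higher, in Ep300 and Prkacb, and its 1 tested member, Prkacb, had an unadjusted limma p above 0.05.

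Rac1 ENSMUST00000080537, of a small GTPase that controls actin assembly, averaged 10.7 ± 5.90 FPKM in the knockout and 47.9 ± 13.04 FPKM in the control (SD, n = 4 per group). Srgap2 ENSMUST00000185596 averaged 1.61 ± 1.4 FPKM in the knockout and 4.84 ± 0.848 FPKM in the control (SD, n = 4 per group). Adjusted p in the authors' deposited table was 0.491 for this Rac1 isoform and 0.888 for this Srgap2 isoform. Neither passed limma adjusted over all transcripts. Axon guidance had 2 higher, both in Sema5a, and 2 lower, in Sema3e and Robo2, and 1 of 2 tested passed adjusted over the list alone. Cell adhesion and extracellular matrix had 3 higher and 1 lower, including Cdh10 isoforms in both directions, and 1 of 3 tested passed adjusted over the list alone.

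Adult neurogenesis had 1 higher and 2 lower. Dcx ENSMUST00000112851, of the immature neuron protein doublecortin, averaged 0.654 ± 0.230 FPKM in the knockout and 0.0391 ± 0.0782 FPKM in the control, and Ccnd2 ENSMUST00000201637 averaged 1.33 ± 0.391 and 2.79 ± 0.477 FPKM (SD, n = 4 per group). The 1 tested member, Ccnd2, had an unadjusted limma p under 0.05. Granule cell markers had 1 lower, Prox1 MERGE.1807.3, at 6.26 ± 6.22 FPKM in the knockout and 14.5 ± 5.32 FPKM in the control (SD, n = 4 per group). Its unadjusted limma p was under 0.05. CA3 and CA2 markers had 1 of each direction (Prkcd higher, Grik4 lower), and 0 of 2 tested passed in limma adjusted over the list alone, with 1, Grik4, at an unadjusted p under 0.05. CA1 markers had 1 higher (Mpped1) and subiculum markers had 1 lower (Nts), both with an unadjusted limma p above 0.05.

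Markers of other cells were listed in both directions, and none passed limma over all transcripts. Astrocyte markers had 1 higher (Agt), oligodendrocyte precursors 1 higher (Lhfpl3), microglia 2 lower (Csf1r among them) and endothelial and mural cells 3 higher (Tagln, Ly6c1 and Acta2). Myelin genes had 2 higher, both isoforms of Plekhb1, and 1 lower, Mag. Plekhb1 ENSMUST00000107046 averaged 43.1 ± 16.7 FPKM in the knockout and 18.4 ± 3.46 FPKM in the control (SD, n = 4 per group). Ependymal markers had 1 of each direction, both models of Foxj1, and meningeal markers had 2 higher, Serping1 and Col1a2. Adjusted over the list alone, 1 of 2 tested transcripts passed in each of the endothelial and ependymal lists and 2 of 3 in the myelin list. The 1 tested member of the astrocyte, microglia and meningeal lists each had an unadjusted limma p under 0.05. Thalamic markers had 1 higher and 2 lower and the 1 tested member, Prkcd, had an unadjusted limma p above 0.05. Neocortical markers had 2 higher and 4 lower, with Lamp5 transcripts in both directions, and 2 of 3 tested passed adjusted over the list alone.

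Cytosolic ribosomal proteins had 4 higher and 7 lower, and 9 of 11 tested passed adjusted over the list alone. Rps15 ENSMUST00000068408 averaged 272 ± 53.2 FPKM in the knockout and 99.7 ± 45.5 FPKM in the control, while the Rps15 model MERGE.2653.1 averaged 31.9 ± 24.2 and 92.9 ± 40.5 FPKM (SD, n = 4 per group). The nuclear-encoded respiratory chain had 4 higher and 2 lower, including Ndufa12 and Atp5h higher and Cox7b lower, with 3 of 3 tested passing adjusted over the list alone. Interferon response had 1 higher (Psmb9) and 2 lower (Ifi27 among them) with 1 of 2 tested passing adjusted over the list alone. Heat shock genes had 1 higher (Cryab), with an unadjusted limma p under 0.05. Genes flanking Jade2 had 1 lower, the Cdkl3 model MERGE.3735.10, which was not tested. The sex-linked check list had 1 lower, Kdm5c ENSMUST00000082177, also not tested. No transcript was listed for interneuron, immediate early, choroid plexus, blood, striatum or mitochondrially encoded genes.

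**Figure D3:**
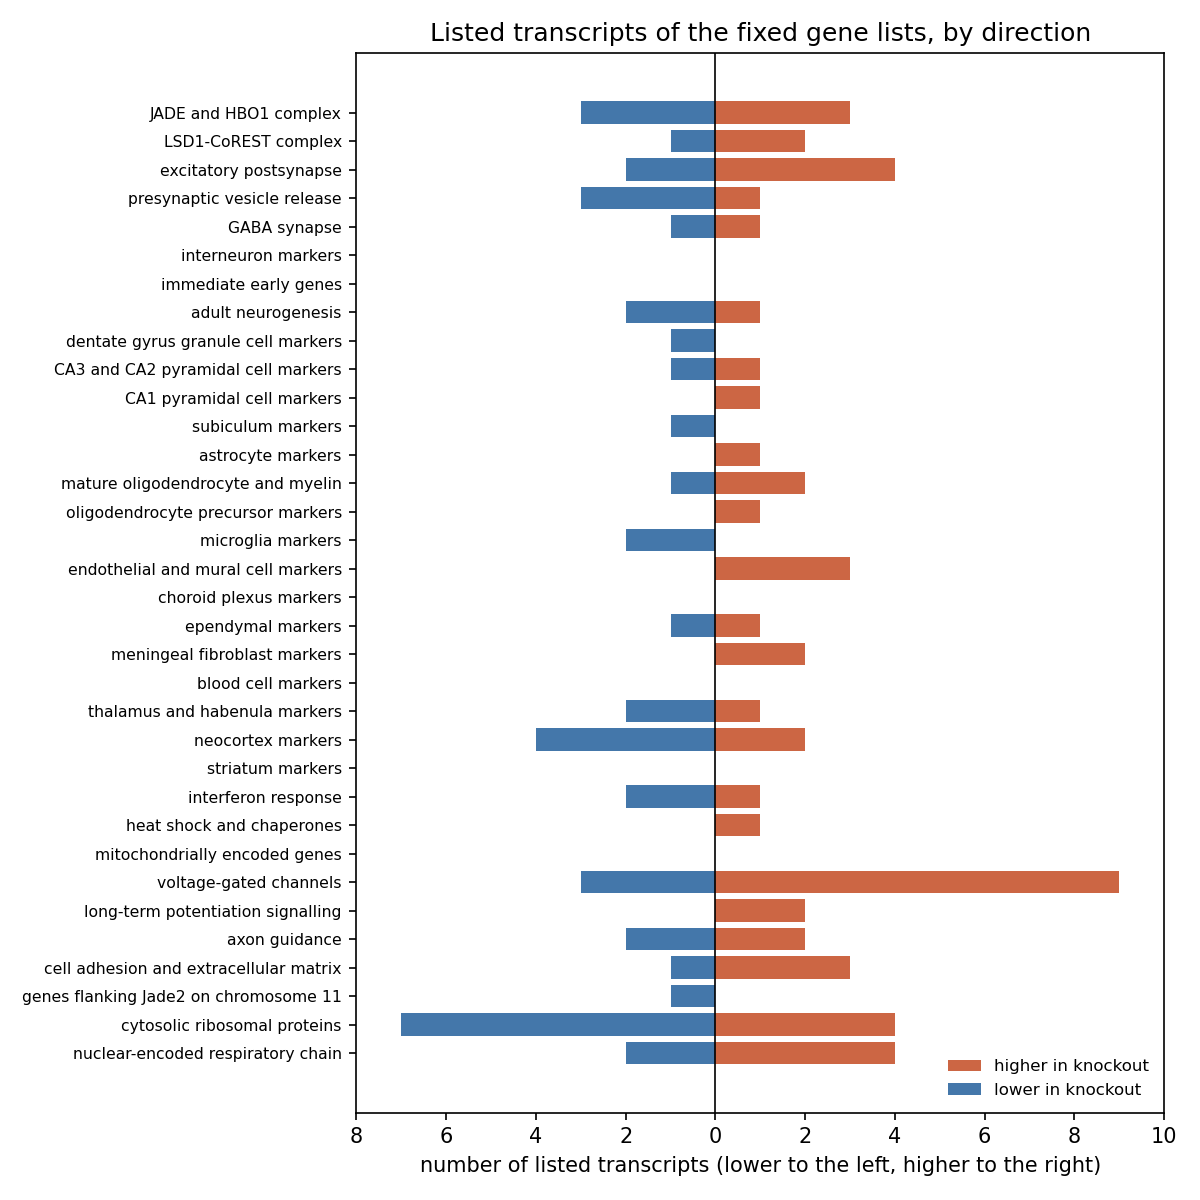
Number of listed transcripts of the fixed gene lists described here (the sex-linked check list is left out), with bars to the right for transcripts higher in the knockout and to the left for lower. Voltage-gated channels have 9 higher and 3 lower, cytosolic ribosomal proteins 4 higher and 7 lower, and 6 lists have none.

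Only 3 lists had the 5 tested members needed for a set test with camera. None passed: the p was 0.764 for the excitatory postsynapse, 0.757 for voltage-gated channels and 0.624 for ribosomal proteins. The median log2 difference of the ribosomal transcripts was -1.19 and the mean -0.08, so no direction is given for this list. With a mean of at least 5 FPKM, 6 ribosomal transcripts had a median of 0.17 and a mean of 0.58. For the 11 ribosomal transcripts of the reported test, the mean difference was 0.11 without knockout replicate 2 and 0.01 without control replicate 3. The median of these 11 stayed negative without either library. With an estimated correlation the adjusted p was 0.788 for all 3, and with fry it was 0.666. Camera compares listed transcripts with other listed transcripts, and fry tests for a shift of the set itself.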

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

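The choice of the library gap as a measure was made before the data were examined, and no test in this part was chosen only after a result was seen. In 38 of 173 groups of 4 values for named transcripts, 1 library lay far from the other 3, with a gap of more than 0.829 of the group's range. Chance would give about 8.65 such groups if values were normally distributed. Many of these abundances are at or near 0, so an excess over chance cannot be read from the count. Knockout replicate 1 was the distant library in 8 of them, control replicate 3 in 7 and control replicate 1 in 6, and groups with 3 values at or near 0 reach a gap of 1.00 with any small value in the remaining library.

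Among the transcripts named for their small p, the gaps were 0.849 for Dis3l (control replicate 3), 1.00 for Matr3 and Jade2 MERGE.3721.8 (knockout replicate 4), 0.997 for Mtcl1 (knockout replicate 2), and 1.00 for Eif4e (control replicate 3), Nbas and Upp1 (control replicate 1). For Matr3, Jade2, Eif4e, Nbas and Upp1 the distant value was at most 0.0235 FPKM.

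Among synaptic and channel genes the gap was 0.997 for Grik4, 1.00 and 0.974 for the Nrxn2 isoforms ENSMUST00000113461 and ENSMUST00000128272, 0.911 for Erc2, 1.00 for Kcnh7 and Scn8a, 0.949 for Kcna2 and 0.879 for Prkacb. The Grik4 model was at 5.24 FPKM in knockout replicate 1, and Prkacb was at 28.6 FPKM in control replicate 2.

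It was 0.999 for Rac3 and 0.996 for Rock1, both in knockout replicate 1, and 0.954 and 0.835 for Sema5a. Among neurogenesis and hippocampal markers it was 1.00 for Dcx, 0.938 for Ccnd2, 0.920 for Prkcd and 0.839 for Mpped1. Prkcd was at 30.3 FPKM in knockout replicate 3, and Mpped1 at 81.0 FPKM in control replicate 4.

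Among markers of other cells it was 0.922 for Plekhb1, 0.945 in the knockout and 0.933 in the control for Csf1r, 0.902 for Ly6c1, 0.908 for Acta2, 0.969 for Serping1, and 0.966, 1.00 and 0.907 for the Lamp5 transcripts. Csf1r was at 21.3 FPKM in control replicate 1. It was 1.00 for the Cdkl3 model beside Jade2, 0.985 for Rps16, 0.846 in the knockout and 0.913 in the control for Rps15 MERGE.2653.1 and 0.976 for Ndufa12.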

How the results depend on the processing

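Adjustment over listed transcripts only, unmoderated variance, sums per locus and the left-out libraries for the Jade2 locus sum were chosen after seeing the data. Jade2 expression, measured by the annotated transcript, kept its direction in every alternative run, from -4.79 with a pseudocount of 0.1 to -1.90 with 1. Its direction could hardly reverse, as this transcript was at 0 in every knockout library and above 0 in every control. With the replicate number as a block its log2 difference was -2.68 with an exact sign-flip p of 0.125, the smallest that 16 sign flips can give. The block gave 0 limma calls, with 519 transcripts at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated between -0.0332 and 0.041, and 1 of 4 control libraries correlated best with its own number. These values show no sign of pairing. They cannot exclude it, because the transcripts were selected on the group difference.

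The count of limma calls was 0 in the reported test, 7 with no filter, 3 at an adjusted p of 0.1, 1 with unmoderated variance and 185 when adjusted over listed transcripts only. Leaving out 1 library gave 0 to 4 calls, with 4 without control replicate 2 and 1 each without control replicate 1 and without control replicate 4. In simulation most calls adjusted over listed transcripts only were false, so 185 is not a count of differences. The count was 0 in limma with the other pseudocounts, scalings, limma settings, a mean of at least 5 and sums per locus, with 138 to 605 at an unadjusted p under 0.05. For the other changes of count the cause was not tested. Of the 7 calls without the filter, 6 have an adjusted p under 0.05 in the authors' deposited table.

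Among 54 named transcripts with a limma result, 0 reversed in direction and 33 results moved past the threshold over all settings, 26 of them with the adjustment over listed transcripts only, 5 with no filter, 1 with unmoderated variance and 1 without control replicate 2. No list passed camera in any alternative run. With fry and no filter together, the adjusted p was 0.0246 for voltage-gated channels. DESeq2 and edgeR were not run because the table holds no counts. The unknown depth limits what a value of 0 means.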

Other observations

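The tests on the Jade2 locus, on the number of loci with both directions, on noncoding isoforms other than retained introns, on 1 retained-intron transcript per locus, on the chromosome 11 window and on other splits of the samples were chosen only after the result was seen. Tmcc2, Mtcl1, Desi1 and Ep400 each had listed isoforms in opposite directions. Tmcc2 ENSMUST00000132435 averaged 53.6 ± 10.3 FPKM in the knockout and 10.9 ± 8.11 FPKM in the control, while ENSMUST00000045473 averaged 14.5 ± 4.30 and 59.5 ± 13.1 FPKM (SD, n = 4 per group). Their sum was 68.1 ± 12.6 FPKM in the knockout and 70.3 ± 19.3 FPKM in the control (SD, n = 4 per group, exact permutation p = 0.886). For Mtcl1 the sums were 6.76 ± 1.27 and 6.64 ± 1.58 FPKM (SD, n = 4 per group, exact permutation p = 0.914). For Fermt3, an integrin regulator of blood cells, the sum was 2.16 ± 0.136 FPKM in the knockout and 1.56 ± 0.214 FPKM in the control (SD, n = 4 per group, exact permutation p = 0.0286, unadjusted and the smallest possible). These loci were picked for their opposite directions.

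In the Jade2 locus the annotated transcript was at 0 in the knockout and unannotated models were present. The knockout to control ratio of the summed listed transcripts was 1.28, which argues against loss of transcription of the whole locus. The count of libraries out of place for the annotated transcript was 0, which argues against a swap of libraries between the groups. Whether total output of the locus was lower cannot be told apart from no difference with these samples, as the exact permutation p of the sums was 0.457. A candidate explanation, not tested because exons of the models are not given, is transcription through an altered allele.

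Of 214 loci with at least 2 listed transcripts, 138 (64.5%) had both directions, against a mean of 120 when directions were shuffled. A share of 0.0061 of 10000 shuffles had as many, which argues against directions independent of the locus. The median absolute log2 fold change was 0.309 for the sums and 1.63 for the larger single transcript, but a small sum is built in for loci picked for opposite directions, so a change of the whole locus stays open. Within groups, the 193 opposite pairs had a median correlation of -0.370, below the range of -0.125 to 0.129 for pairs from different loci, so reads divided differently among overlapping models from library to library may account for part of the pattern. Isoform use that differs by genotype stays open and was not tested.

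Retained-intron transcripts were higher in the knockout in 123 cases and lower in 83, against 340 and 368 for protein-coding transcripts (odds ratio 1.60, 95% interval 1.16 to 2.23, Fisher's exact p 0.00338, adjusted 0.0102 over 3 isoform classes). All these transcripts come from the same libraries, so the p-value and intervals in this paragraph do not measure the spread between samples. With abundance and length in a logistic model the odds ratio was 1.86 (1.32 to 2.61), which argues against abundance or length as the whole cause. More unspliced or partly processed RNA of every kind was left undecided by the test first set for it, an odds ratio of 0.770 (0.538 to 1.10) for nonsense-mediated decay and processed-transcript isoforms. After that result, a direct comparison of retained-intron with those isoforms was added and gave 2.08 (1.35 to 3.23), and as it was picked with both sets of counts in view it does not settle the question. More intron retention in the knockout may be proposed as a hypothesis only, since transcripts were selected on p. With 1 transcript per locus and class the odds ratio was 1.68 (1.21 to 2.36). This adds little, as 122 higher and 80 lower retained-intron transcripts remained.

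A hypothesis that variants carried along with the targeted allele put more listed genes near Jade2 was tested in a window of 5 Mb on each side. Of 141 protein-coding genes there 3 had a listed transcript, against 110 of 1497 on the rest of chromosome 11 (odds ratio 0.274, 95% interval 0.0550 to 0.841, Fisher's exact p 0.0144), the opposite of that prediction, although genes silent in hippocampus were not set apart. The genes share the same libraries, so this p does not measure the spread between samples.

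The real split of the 8 libraries gave 0 limma calls and the highest other split gave 0. Each of the 35 splits reaches a count of 0 by construction, so this comparison says nothing about chance. In the list 606 transcripts (36.1%) had groups that do not overlap, against 2.86% by chance, but the list was selected on the group difference.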
